A study of Mus musculus with 16 samples.

How the data were processed

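RNA from 16 mouse melanoma biopsies was measured on 2-colour Agilent arrays, with the tumour RNA in Cy5 and a pooled mouse reference RNA in Cy3 on every array. The labels place 4 tumours in each of 4 groups, which are untreated tumours, tumours after 4 and after 60 days of a BRAF inhibitor, and resistant tumours at 120 days. The name of the drug is not given in the sources used here. The arrays lay on 2 slides, each with 2 arrays of every group, so slide and group could be separated. Replicates 3 and 4 of each group were on slide 1, and replicates 1 and 2 were on slide 2. The position within a slide followed the group and could not be separated from it. All arrays had the reference in the same dye. The sample titles also carry codes, whose meaning (animal, cage or litter) is not given in the sources used here. In the 60-day and in the resistant group 2 tumours share 1 code and the other 2 another, and the codes follow the slides. In the untreated group 3 tumours share a code, and the 4-day tumours have a series of codes of their own. The tests treat the tumours as independent, and standard errors would be too small if tumours with 1 code were not.

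Per the file headers, the spot values are intensity values, as the mean brightness of each spot and the median brightness of its local background, read by Agilent Feature Extraction 10.7.3.1. Per the file headers, the same software also gave processed intensity values after background subtraction, detrending and dye normalization, and their log10 ratio of Cy5 over Cy3. Per the file headers, further columns of another kind (other) hold flags of 0 or 1 for spots above background, not uniform or saturated. The deposited value table holds log2 ratios of Cy5 over Cy3, which matched the log10 ratios after a change of base with a slope of 0.993. It lacked between 21.6% and 40.2% of its values per array, by a rule not given in the sources used here. The table was not centred, with array medians from -0.194 to -0.0638.

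The mean spot intensities and the median backgrounds were read again from each array. Background was removed with the normexp method with an offset of 50, the Cy5 over Cy3 ratio was normalized within each array by loess, and values were expressed as log2 ratios with limma 3.58.1 in R 4.3.3. Control spots had no weight in the loess and were then dropped. Spots flagged as outliers by Feature Extraction were treated as missing, and this affected 0.144% of the values analysed. The 59305 spots of an array were averaged to 55681 probes. A probe was kept when its Cy5 signal was above background on at least 4 of the 16 arrays, which left 30501 probes. Probe symbols were updated through RefSeq accessions for 28026 probes, which changed 1651 symbols. For each gene the probe with the highest mean intensity was used, which gave 21951 genes and transcripts for testing, of which 15879 carry a symbol of the RefSeq table. Chromosome positions are those of the array design, on mouse build mm9.

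Group differences were tested with limma with the 4 groups in 1 model, and p-values were adjusted by the Benjamini-Hochberg method in each comparison, with a threshold of 0.05. Each difference is given as log2 with its standard error from limma, over 4 arrays against 4. For a probe above background on no array of a group, the fold in Cy5 sets the other group's mean against the higher of the probe's signal and the lowest signal above background, after loess and Aquantile. It leaves the reference out and is open to dye bias, so "at least" is written only where it is below the fold of the ratio. All 6 pairs of groups were compared. The groups of the comparisons, the gene lists, the rule for naming genes and the alternative settings were fixed before the data were examined, except where stated.

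There were 32 gene lists, and a list needed at least 5 measured members. They covered MAPK output, melanocyte pigment, receptors and dedifferentiation linked to BRAF inhibitor resistance, cell cycle, granulocytic myeloid cells, monocytes and macrophages, myeloid suppressive effectors, myeloid chemokines and growth factors, T cells, cytotoxic and NK cells, regulatory T cells, immune checkpoints, B and plasma cells, dendritic cells, mast cells, MHC class I and class II presentation, interferon response, complement and coagulation, fibroblasts and matrix, pericytes and smooth muscle, endothelium, keratinocytes, hair follicle shaft, sebaceous gland, skeletal muscle, adipocytes, nerve and Schwann cells, erythroid blood cells, hypoxia and glycolysis, oxidative phosphorylation, and immediate early and heat shock genes. Each list was compared with the other genes by camera with a preset correlation of 0.01, adjusted over the 32 lists. Camera with the correlation estimated from the data and fry, which tests a list against no change, were run beside it. The mean log2 ratio of a list's members on each array was compared between groups by an exact two-sided permutation test over the 70 splits of 8 arrays, whose smallest p is 0.0286. A further list of 5 sex-linked genes was used only to look for exchanged samples. Xist was above background on 16 arrays, Ddx3y and Eif2s3y on 1 array each, and Kdm5d and Uty on 0, and no test was made.

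Genes were named by a fixed rule. In each comparison these were the 10 largest rises and the 10 largest falls past the threshold whose groups did not overlap, without transcripts that have no gene name. Where fewer than 3 genes passed, the 5 with the smallest p were taken. From each list discussed, up to 4 members past the threshold with the largest difference were named, or the 2 brightest members where none passed. The genes Dusp6, Spry4, Etv5, Mitf, Tyr, Dct, Mki67, Ccl2, Ccr2, Csf1r, S100a8, S100a9, Arg1, Foxp3, Cd8a, Cd3e, Gzmb, Cd274 and Braf were named whatever their values. Of the genes this rule names, 2 are not reported here, although counts of named genes include them.

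A day-4 signature was built without using the same arrays to choose and to score. The 100 genes with the highest and the 100 with the lowest moderated statistic of limma for 4-day against untreated on 1 slide were scored on the other slide. The score is the mean of the genes chosen as high and of the sign-turned genes chosen as low, centred over the groups on each slide, and is given relative to the mean of the untreated arrays.

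The pipeline was tested on simulated data, with the spread fitted for each gene, independent noise and known changes added to 1 group. Between 4-day and untreated arrays, 72% of 2-fold and 92% of 4-fold changes were recovered, with 5 false calls among 21951 genes. For resistant against untreated arrays they were 66% and 90%, with 11 false calls. A signature shift of 50% gave 50.5% and of 0% gave 0.556%, which checks the code and not precision in the data.

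Median Cy5 intensity lay between 80.6 and 110 on the 16 arrays, and between 49.1% and 54.2% of probes were above background in Cy5. The number of arrays limits the precision. No array was left out. The columns written by the scanner software for saturated spots were not used, as at most 2 Cy5 spots of an array were saturated.

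The alternatives were processed signals of Feature Extraction, no background correction, Aquantile normalization between arrays, median centring in place of loess, the Cy5 channel alone, the deposited value table, no filter on dim probes, a filter for probes above background on all arrays, the slide as a block, the mean of a gene's probes, limma with a trend and robust variance, a model with only the 2 groups compared, array weights, each array left out in turn, and signatures of 50 and 250 genes in each direction. Each slide alone and the permutation test of list scores as a count of calls were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3 for reading, and the R package data.table, version 1.17.8, was used for reading in R.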

Results

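Whole-tissue RNA of 16 mouse melanoma biopsies was profiled against a common reference RNA, with 4 tumours in each of 4 groups. The groups were untreated tumours, tumours treated with a BRAF inhibitor for 4 or for 60 days, and tumours that had acquired resistance by day 120. Values are log2 differences ± SE between groups of 4 arrays, unless another unit is given. Arrays of the same group had a median correlation of 0.894 and arrays of different groups 0.869, across genes, which are not independent replicates. The lowest correlation between any pair of arrays was 0.577. On the leading principal component (39.9% of the variance) resistant replicate 1 lay farthest out, at 91.9. Untreated replicate 3 lay at -19.3, and the other untreated arrays at 33.6 to 57.7. The slide explained 0.649 of the variance of the next component. Of 21951 genes and transcripts tested, 293 changed between 4-day and untreated tumours, 179 between 60-day and untreated tumours, and 4 between resistant and untreated tumours.

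The comparison of 4-day with untreated tumours asks what a short course of BRAF inhibition does to the tumour and its surroundings. After 4 days, the lists of MAPK output and cell cycle genes were lower by camera with a fixed correlation, but not with an estimated correlation (adjusted p = 0.187 and 0.511). The sample titles give the 4-day tumours another series of codes than all other tumours, so a difference in origin or handling of these animals cannot be told apart from 4 days of treatment. The gene Dbp, a circadian transcription factor on chromosome 7 (probe at 52965322 to 52965381), rose 9.86-fold (3.30 ± 0.36, adjusted p = 0.00118). Ccnd1, which encodes cyclin D1 and depends on MAPK signalling (chromosome 7, 152116202 to 152116261), fell 5.27-fold (-2.40 ± 0.30, adjusted p = 0.00224). Adamts4, a protease that cleaves matrix proteoglycans, fell 6.80-fold (-2.76 ± 0.33, adjusted p = 0.00164). Adh1, an alcohol and retinol dehydrogenase, rose 5.01-fold (2.32 ± 0.26, adjusted p = 0.00122).

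Of the 293 genes, 91 rose and 202 fell, and 125 changed at least 2-fold. Among the largest rises were Tef (1.71 ± 0.28) and Hlf (1.72 ± 0.34), which encode transcription factors of the same family as Dbp. Inmt, a methyltransferase gene, rose by 2.41 ± 0.50, the peptide transporter gene Slc15a2 by 2.22 ± 0.48, Pamr1 by 1.95 ± 0.42, the gasdermin gene Gsdma2 by 1.91 ± 0.41, and Tsc22d3, a target of glucocorticoids, by 1.68 ± 0.37. Adjusted p for these genes lay between 0.013 for Tef and 0.0447 for Tsc22d3. Among the largest falls were the collagenase gene Mmp13 (-1.94 ± 0.41), the collagen gene Col8a1 (-1.87 ± 0.37), the proteoglycan gene Vcan (-1.84 ± 0.30) and the membrane protease gene Adam19 (-1.94 ± 0.28). For Adam19 another probe gave -0.54, and for Vcan the other probes gave -0.97 to -0.64. The remaining large falls were in Tmem200a (-2.37 ± 0.25), the natriuretic peptide gene Nppb (-2.06 ± 0.47), Klhl30 (-1.92 ± 0.39) and Spry4 (-1.87 ± 0.36). The adjusted p of these 8 falls lay between 0.000787 for Tmem200a and 0.049 for Nppb. All of these genes had the same direction on both slides, which the naming rule ensures, as their groups do not overlap. The smallest within-slide difference was -1.15 on slide 2, for Nppb.

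The count of 293 was 632 (204 higher and 428 lower) with the slide as a block, and these held all 293. At an unadjusted p under 0.05 there were 3670 genes, with 1098 expected by chance. The groups did not overlap for 276 of the 293 genes, and for 6.99% of all genes, where chance gives 2.86%. The log2 differences of the slides had a correlation of 0.589 across genes. The count fell to 44 without untreated replicate 2 or 4, 52 without 4-day replicate 4, 59 without untreated replicate 1, 60 without 4-day replicate 1, 193 without 4-day replicate 2, between 135 and 155 without any 60-day replicate (146, 155, 137 and 135 without replicates 1 to 4), 187 without resistant replicate 2 and 147 without resistant replicate 4. It rose to 500 without 4-day replicate 3, 678 without untreated replicate 3 and 695 without resistant replicate 1. It was 12 with median centring, 29 in a model of these groups alone, 71 with processed signals of Feature Extraction, 105 in the deposited value table, 513 with Cy5 alone, 4699 with array weights and 0 on either slide alone. Dbp, Adh1, Tef, Adamts4, Ccnd1, Tmem200a and Adam19 passed without any single array, while as few as 8 of the 20 named genes passed without 4-day replicate 4 or untreated replicate 2 or 4.

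**Figure D1:**
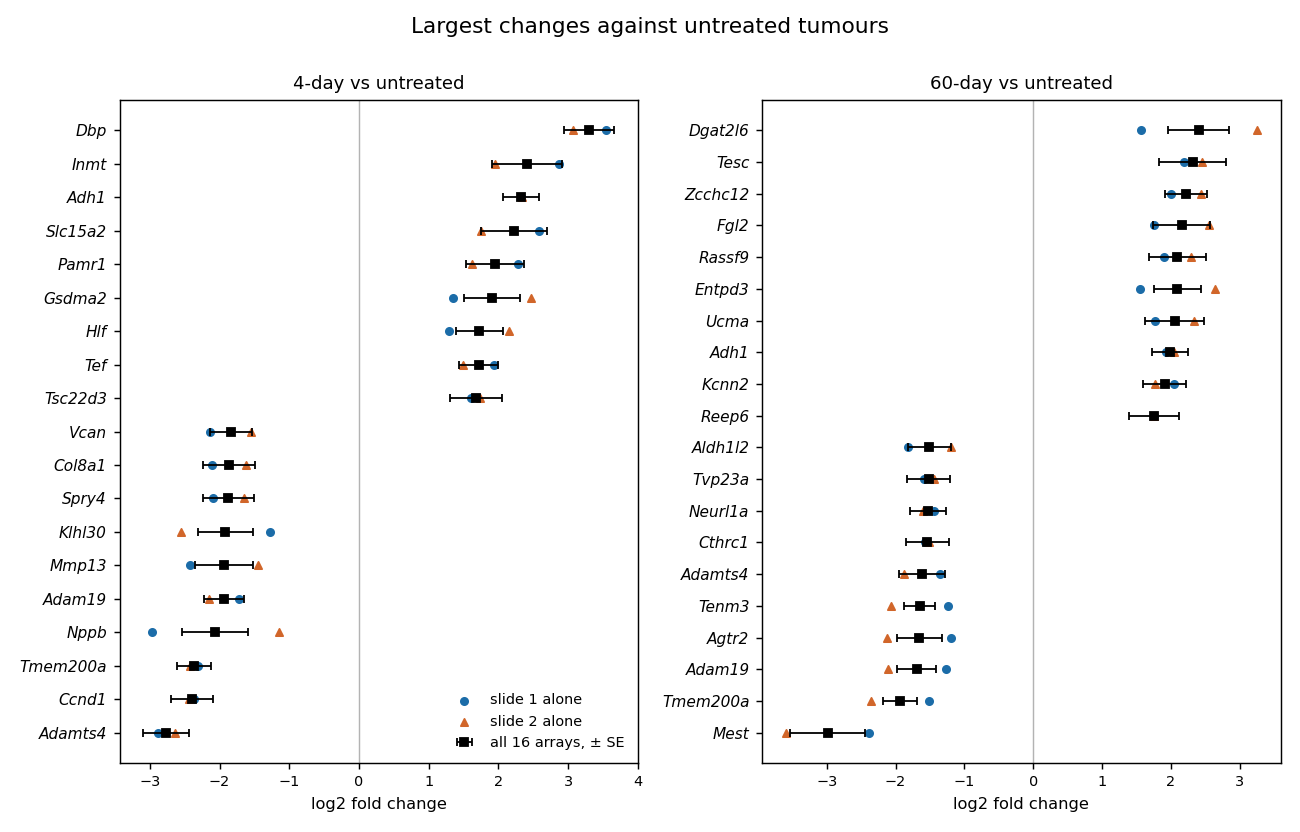
Log2 difference from untreated tumours (x axis) of the named genes with the largest changes (y axis) at 4 days and at 60 days, as mean ± SE of 4 against 4 arrays, with the differences within slide 1 and within slide 2 as separate points. Dbp had the largest rise at 4 days (3.30) and Mest the largest fall at 60 days (-2.99).

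MAPK output genes, which respond to signalling downstream of BRAF, fell as a group at 4 days (mean difference -0.66 ± 0.11, lower in 14 of 16 measured members, camera adjusted p = 1.25e-05, adjusted p = 0.187 with an estimated correlation). Members past the threshold were Ccnd1, Spry4 and Dusp6, which fell by 0.94 ± 0.19 (adjusted p = 0.0341), and 6 fell when adjusted over the list alone. Spry4 and Dusp6 encode feedback inhibitors of the pathway. The list lay lower in 4 of 4 4-day tumours than in any untreated tumour (exact permutation p = 0.0286), at -0.82 on slide 1 and -0.51 on slide 2. Fry gave an adjusted p of 0.00422. Etv5, another target, had a difference of -0.96 ± 0.29 (adjusted p = 0.127). Spred1 (-0.92 ± 0.22, adjusted p = 0.0542, or 0.00325 adjusted over the list alone) was picked after its values were seen.

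Cell cycle genes were lower at 4 days by a mean of -0.66 ± 0.22, with a negative difference in all 28 measured members (camera adjusted p = 1.3e-16, adjusted p = 0.511 with an estimated correlation). The transcription factor gene E2f1 (-0.83 ± 0.14, adjusted p = 0.0134) and the replication helicase genes Mcm4 (-0.72 ± 0.16), Mcm6 (-0.70 ± 0.15) and Mcm3 (-0.67 ± 0.12) passed, as did Pcna, and 20 fell when adjusted over the list alone. The shift was -0.63 on slide 1 and -0.69 on slide 2 (exact permutation p = 0.0286). Mki67, a marker of dividing cells, had a difference of -0.68 ± 0.44 (adjusted p = 0.482).

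Melanocyte pigment genes were higher by a mean of 0.88 ± 0.32 at 4 days, in 15 of 16 members (camera adjusted p = 9.72e-07, adjusted p = 0.511 with an estimated correlation). Mitf, the transcription factor that governs this lineage, rose 1.84-fold (0.88 ± 0.20, adjusted p = 0.046), and 7 members rose when adjusted over the list alone. The difference was 0.71 ± 0.32 for Tyr, the enzyme of melanin synthesis (adjusted p = 0.29), and 0.75 ± 0.70 for Dct (adjusted p = 0.678). The group shift was 0.51 on slide 1 and 1.25 on slide 2 (exact permutation p = 0.114). Markers of skin appendages were higher in the same tumours. Sebaceous gland genes were higher by a mean of 1.11 ± 0.21 (camera adjusted p = 1.81e-05, adjusted p = 0.511 with an estimated correlation), with Scd1, a fatty acid desaturase gene, past the threshold (1.37 ± 0.30, adjusted p = 0.0428) and 5 members adjusted over the list alone. Their shift was 0.88 on slide 1 and 1.33 on slide 2 (exact permutation p = 0.0286). Hair shaft genes were higher by a mean of 1.77 ± 0.91, with a positive difference in 16 of 16 members (camera adjusted p = 4.22e-07, adjusted p = 0.644 with an estimated correlation). None passed singly in limma or adjusted over the list alone, and the shift was 1.88 on slide 1 and 1.66 on slide 2 (exact permutation p = 0.143). Its brightest members, the keratin genes Krt27 and Krt71, had 1.82 ± 0.70 and 1.18 ± 0.49. Adipocyte genes had a mean difference of 0.64 ± 0.53, with 1.22 on slide 1, 0.06 on slide 2, 0.35 without 4-day replicate 1 and 1.12 without 4-day replicate 2 (camera adjusted p = 0.000469, adjusted p = 0.644 with an estimated correlation). Pnpla2, a triglyceride lipase gene, rose by 0.87 ± 0.19. This list did not pass with processed signals of Feature Extraction (adjusted p = 0.0894) or the deposited value table (adjusted p = 0.109), in a range of 5.58e-06 to 0.644 over its alternatives.

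Several immune lists and the fibroblast list were lower at 4 days. Interferon response genes were lower by 0.58 ± 0.28 (25 of 26 members lower, camera adjusted p = 2.6e-07, adjusted p = 0.625 with an estimated correlation), and the shift was -0.71 on slide 1 and -0.46 on slide 2 (exact permutation p = 0.114). Irf1 (-1.06 ± 0.31, adjusted p = 0.113) and Isg15 (-0.75 ± 0.26, adjusted p = 0.167) were its brightest members, and 3 fell when adjusted over the list alone. Fibroblast and matrix genes were lower by 0.66 ± 0.41 (18 of 20 lower, camera adjusted p = 5.76e-05, adjusted p = 0.644 with an estimated correlation), with -0.55 on slide 1, -0.76 on slide 2 and -0.40 without 4-day replicate 4. None passed in limma, and 7 fell when adjusted over the list alone. Sparc (-0.47 ± 0.64) and Col1a2 (-0.53 ± 0.48) were the brightest. Myeloid chemokines and growth factors were lower by 0.68 ± 0.22 (16 of 18 lower, camera adjusted p = 0.00631, adjusted p = 0.644 with an estimated correlation), with -0.68 on slide 1 and -0.69 on slide 2 (exact permutation p = 0.0571). The chemokine gene Cx3cl1 fell by 0.68 ± 0.15 (adjusted p = 0.046), the only member past the threshold, and 1 fell when adjusted over the list alone. Ccl2, a monocyte chemoattractant, had a difference of -1.16 ± 0.37 (adjusted p = 0.147). This call ended without 4-day replicate 4 (adjusted p = 0.0567), in a range of 1.84e-05 to 0.644.

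A further 5 immune lists were lower at 4 days, but each call ended without at least 1 array, and their ranges of adjusted p over the alternatives reached 0.625 to 0.675. Genes of cytotoxic and NK cells had a mean difference of -0.41 ± 0.26 (camera adjusted p = 0.00459, adjusted p = 0.644 with an estimated correlation), with adjusted p = 0.0609 without 4-day replicate 3, and -0.22 (adjusted p = 0.22) without untreated replicate 3. Gzma, a granule protease gene, fell 2.66-fold (-1.41 ± 0.28, adjusted p = 0.0307), and 2 members fell when adjusted over the list alone. Gzmb was above background in 0 of 4 4-day tumours and did not pass (adjusted p = 0.113). MHC class I genes had -0.37 ± 0.27 (camera adjusted p = 0.00514, adjusted p = 0.644 with an estimated correlation), with -0.23 (adjusted p = 0.0935) without 4-day replicate 1 and -0.21 (0.235) without untreated replicate 3. Checkpoint genes had -0.37 ± 0.19 (camera adjusted p = 0.00602, adjusted p = 0.625 with an estimated correlation), with -0.22 (adjusted p = 0.206) without untreated replicate 3. Monocyte and macrophage genes had -0.37 ± 0.28 (camera adjusted p = 0.0213, adjusted p = 0.675 with an estimated correlation), with -0.19 (adjusted p = 0.288) without 4-day replicate 4, -0.22 (0.178) without untreated replicate 1 and -0.56 without 4-day replicate 3. Its adjusted p was 0.0935 without 4-day replicate 1 and 0.0564 without untreated replicate 3. Myeloid suppressive effectors, the products with which myeloid cells restrain T cells, had -0.40 ± 0.10 (camera adjusted p = 0.036, adjusted p = 0.644 with an estimated correlation), with 0.0886 without 4-day replicate 3, 0.0613 without 4-day replicate 4 and 0.235 without untreated replicate 3. Their within-slide values on slides 1 and 2 were -0.67 and -0.15, -0.54 and -0.20, -0.59 and -0.15, -0.18 and -0.56, and -0.50 and -0.30, in the order above. No member of these lists other than Gzma passed. Differences of single immune genes were -1.11 ± 0.91 for S100a8, -0.53 ± 0.60 for S100a9, -0.64 ± 0.55 for Arg1, -0.43 ± 0.35 for Csf1r, -0.43 ± 0.48 for Ccr2, -0.40 ± 0.21 for Cd8a (above background in 0 of 4 4-day tumours), -0.09 ± 0.30 for Cd3e, -0.25 ± 0.22 for Foxp3 and -0.34 ± 0.34 for Cd274. That of Braf was 0.38 ± 0.20.

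The other 18 lists did not pass at 4 days. Granulocytic genes had a mean difference of -0.47 ± 0.18 (adjusted p = 0.112), dendritic cell genes -0.27 (0.085), T cell genes -0.23 (0.102), regulatory T cell genes -0.16 (0.205), MHC class II genes -0.26 (0.129), complement genes -0.18 (0.312) and hypoxia genes -0.06 (0.546). Keratinocyte genes had 0.37 ± 0.32 (0.202), mast cell genes 0.20 (0.108, or 0.0224 with the slide as a block), immediate early genes 0.21 (0.134), skeletal muscle genes 0.31 ± 0.82 (0.302), oxidative phosphorylation genes 0.07 (0.302), endothelial genes 0.11 (0.312), erythroid genes 0.17 (0.513) and pericyte genes 0.03 (0.891). Genes of receptors and dedifferentiation linked to resistance had -0.08 ± 0.10 (0.648), although Nes, an intermediate filament gene of that list, fell by 1.84 ± 0.42 (adjusted p = 0.0492). Nerve genes had -0.11 ± 0.28 (0.876, with camera and the mean of opposite sign), and their member Fabp7 fell by 1.93 ± 0.42 (adjusted p = 0.0428). B and plasma cell genes had 0.01 ± 0.11 (0.911). The median was of opposite sign to the mean for B and plasma cell genes (-0.02) and erythroid genes (-0.01).

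**Figure D2:**
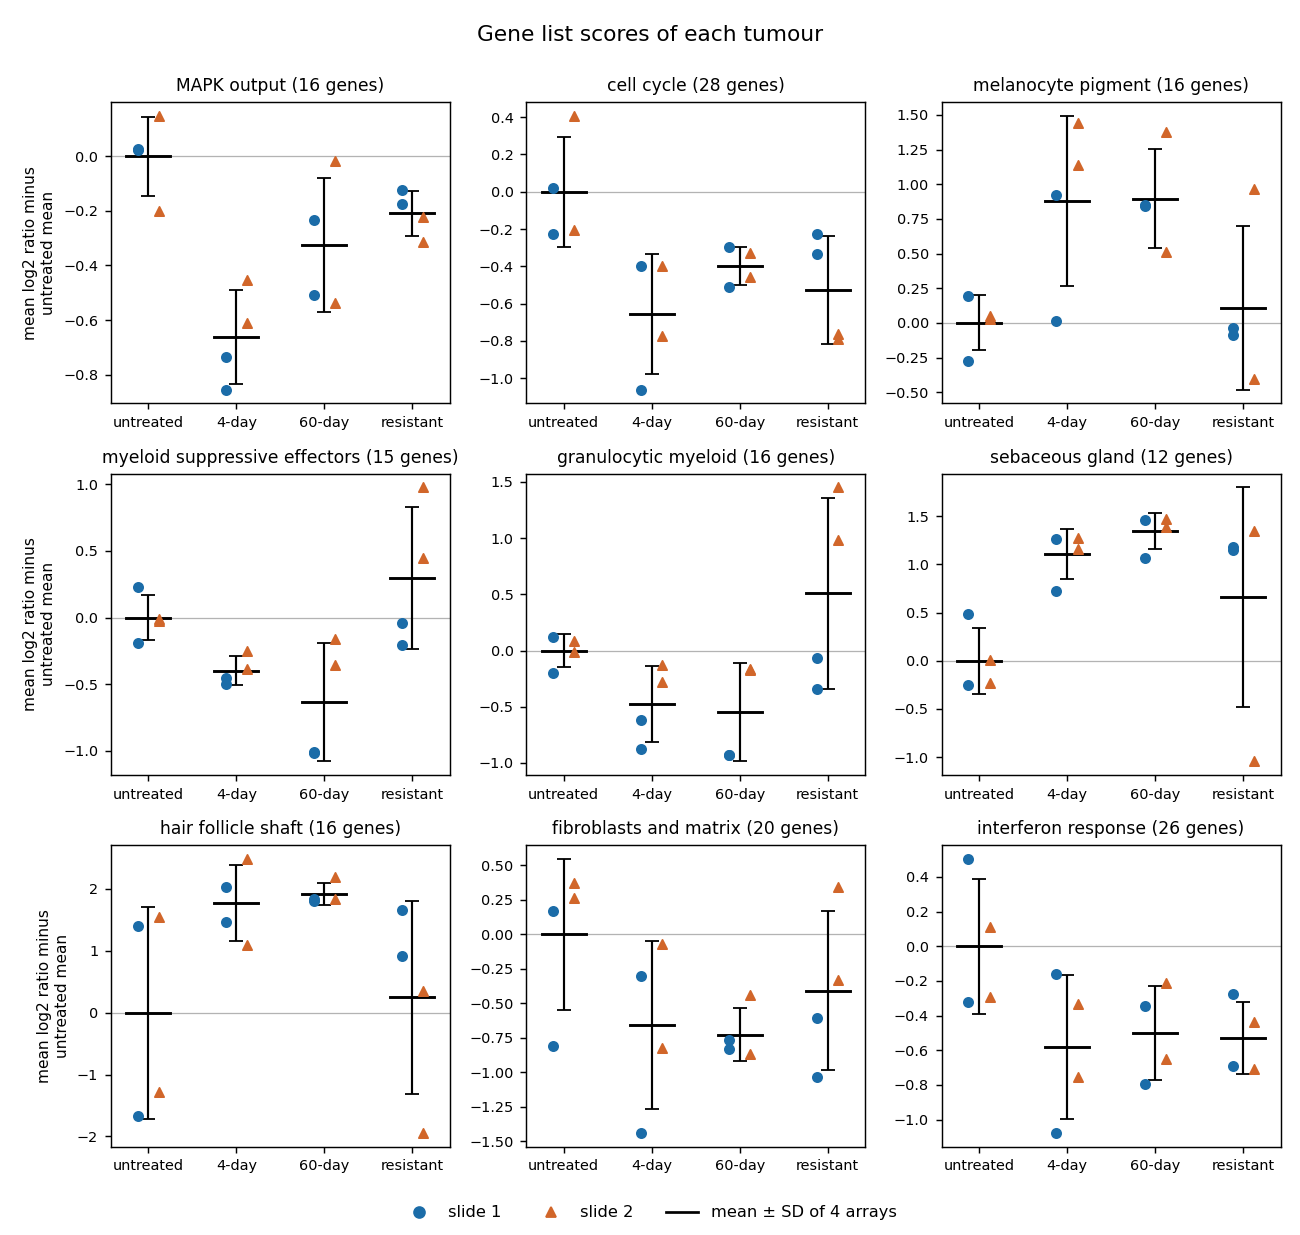
Mean log2 ratio of the members of 9 gene lists in each tumour, relative to the untreated mean (y axis), by group (x axis), with circles for slide 1, triangles for slide 2 and bars for mean ± SD of 4 tumours. MAPK output genes lay lower in all 4 4-day tumours than in any untreated tumour, and the 4 resistant tumours were spread from -0.34 to 1.45 for granulocytic genes.

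The comparison of 60-day with untreated tumours asks which changes are seen under prolonged treatment. Mest, an imprinted gene of embryonic mesoderm (chromosome 6, 30698279 to 30698338), fell 7.93-fold (-2.99 ± 0.54, adjusted p = 0.026). Adh1 rose 3.96-fold (1.99 ± 0.26, adjusted p = 0.0053), and Zcchc12, a zinc finger gene on chromosome X (33739067 to 33739126), rose 4.66-fold (2.22 ± 0.30, adjusted p = 0.0053). Genes of hair, sebaceous glands and pigment were higher as groups, and genes of the cell cycle, interferon response and myeloid chemokines were lower, by camera with a fixed correlation. None of these 6 lists passed with an estimated correlation (adjusted p = 0.538 for each).

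Of the 179 genes, 77 rose and 102 fell, and 95 changed at least 2-fold. Large rises were seen for the acyltransferase-like gene Dgat2l6 (2.41 ± 0.44), the calcium-binding protein gene Tesc (2.32 ± 0.49), Fgl2, which encodes a fibrinogen-like protein secreted by immune cells (2.16 ± 0.42), Rassf9 (2.10 ± 0.42), the ectonucleotidase gene Entpd3 (2.09 ± 0.35), the potassium channel gene Kcnn2 (1.91 ± 0.31) and Reep6 (1.75 ± 0.37). Ucma, a gene of cartilage matrix, was above background in 0 of 4 untreated tumours and rose (adjusted p = 0.0384), 4.64-fold in Cy5 and 4.15-fold in the ratio to the reference. Large falls were seen for Tmem200a (-1.94 ± 0.25), Adam19 (-1.69 ± 0.28), Adamts4 (-1.61 ± 0.33), the cell adhesion gene Tenm3 (-1.65 ± 0.22), Cthrc1, a secreted product of activated fibroblasts (-1.54 ± 0.31), Neurl1a (-1.53 ± 0.26), Tvp23a (-1.52 ± 0.31) and the mitochondrial folate enzyme gene Aldh1l2 (-1.51 ± 0.31). The angiotensin receptor gene Agtr2 was above background in 0 of 4 60-day tumours and fell (adjusted p = 0.0363), 3.21-fold in Cy5 and 3.15-fold in the ratio. Adjusted p for these genes lay between 0.0053 for Tmem200a and Tenm3 and 0.0396 for Tesc and Reep6. All 20 named genes had the same direction on both slides, which the naming rule ensures. The smallest within-slide difference among those above background in all tumours of both groups was -1.20 on slide 2, for Aldh1l2.

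The count of 179 was 615 (268 higher and 347 lower) with the slide as a block, which held all 179. At an unadjusted p under 0.05 there were 4098 genes. The groups did not overlap for any of the 179, nor for 13.8% of all genes, where chance gives 2.86%, and the slides had a correlation of 0.747 across genes. The count fell to 22, 23 and 24 without untreated replicates 2, 4 and 1, to 28, 23, 24 and 27 without 60-day replicates 1 to 4, to 69 without 4-day replicate 1, and rose to 330 without 4-day replicate 3, 1098 without untreated replicate 3 and 1132 without resistant replicate 1. It was 12 with median centring, 28 with processed signals of Feature Extraction, 74 in the deposited value table, 1254 in a model of these groups alone, 5155 with array weights and 0 on either slide alone. Zcchc12, Adh1, Tmem200a and Tenm3 passed without any single array, and only 4 of the 20 named genes passed without 60-day replicate 1 or 3 or untreated replicate 1, 2 or 4.

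The list of hair shaft genes was higher in 16 of 16 members at 60 days (1.92 ± 0.86, camera adjusted p = 4.91e-07, adjusted p = 0.538 with an estimated correlation), and 15 rose when adjusted over the list alone. Its untreated scores ranged from -1.66 to 1.55, and the 60-day shift was 1.95 on slide 1 and 1.88 on slide 2 (exact permutation p = 0.0286). Krt27 (1.83 ± 0.70) and Krt71 (1.15 ± 0.49) did not pass. Sebaceous gland genes had 1.34 ± 0.20 (11 of 12 higher, camera adjusted p = 2.53e-06, adjusted p = 0.538 with an estimated correlation). Slide 1 had 1.15 and slide 2 1.54. Scd1 rose 3.19-fold (1.67 ± 0.30, adjusted p = 0.0251), and 8 members rose when adjusted over the list alone. Keratinocyte genes had 0.61 ± 0.22 (17 of 18 higher, camera adjusted p = 0.0491, adjusted p = 0.902 with an estimated correlation), with 0.43 on slide 1 and 0.80 on slide 2 (exact permutation p = 0.0286). Krt5 and Krt16 had 0.21 and 0.18. The keratinocyte call did not hold with the slide as a block (adjusted p = 0.0696), with fry, under 7 other settings, slide 2 alone among them (0.131), or in 9 of 16 runs without 1 array, in a range of 0.000113 to 0.902. Those runs left out a 4-day replicate (0.0508, 0.0575, 0.0501 and 0.0609 without replicates 1 to 4), 60-day replicate 1 (0.184) or 2 (0.114), resistant replicate 3 (0.0562), or untreated replicate 3 (0.224) or 4 (0.0701). Pigment genes were higher by 0.89 ± 0.20 (15 of 16 members, camera adjusted p = 2.53e-06, adjusted p = 0.538 with an estimated correlation), with 0.89 on slide 1 and 0.90 on slide 2 (exact permutation p = 0.0286) and 5 members adjusted over the list alone. Mitf had 0.49 ± 0.20 (adjusted p = 0.202), Tyr 0.68 ± 0.32 and Dct 0.95 ± 0.70.

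Cell cycle genes were lower at 60 days by a mean of -0.40 ± 0.16, with a negative difference in 28 of 28 members (camera adjusted p = 4.91e-07, adjusted p = 0.538 with an estimated correlation), with -0.30 on slide 1, -0.49 on slide 2 (exact permutation p = 0.0286) and -0.26 without untreated replicate 1. E2f1 fell by 0.88 ± 0.14 (adjusted p = 0.0145) and Mcm3 by 0.59 ± 0.12 (adjusted p = 0.0384), and 5 members fell when adjusted over the list alone. MAPK output genes had -0.32 ± 0.14 (12 of 16 lower, camera adjusted p = 0.0227, adjusted p = 0.538 with an estimated correlation), with -0.40 on slide 1 and -0.25 on slide 2 (exact permutation p = 0.0571). Dusp6 fell 1.98-fold (-0.98 ± 0.19, adjusted p = 0.0345), and 4 members fell when adjusted over the list alone. Spry4 had -0.89 ± 0.36 (adjusted p = 0.208) and Etv5 -0.66 ± 0.29 (adjusted p = 0.242). The MAPK call ended without 60-day replicate 2 (adjusted p = 0.0512) or 3 (0.0531) or untreated replicate 2 (0.0503) or 3 (0.102), and with array weights (0.0647), in a range of 0.00311 to 0.538. Mki67 had -0.29 ± 0.44 and Braf 0.27.

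Several immune lists and the fibroblast list were lower at 60 days, while mast cell genes were higher. Myeloid chemokines and growth factors were lower by 0.84 ± 0.19 (17 of 18 lower, camera adjusted p = 0.00246, adjusted p = 0.538 with an estimated correlation), with -1.05 on slide 1 and -0.63 on slide 2 (exact permutation p = 0.0286). Its member Il34, a growth factor for macrophages, rose 2.01-fold (1.01 ± 0.16, adjusted p = 0.0145), and adjusted over the list alone 1 member rose and 1 fell. Interferon response genes were lower by 0.50 ± 0.24 (24 of 26 lower, camera adjusted p = 2.35e-05, adjusted p = 0.538 with an estimated correlation), with -0.66 on slide 1, -0.34 on slide 2 (exact permutation p = 0.114), -0.33 without untreated replicate 3 and 3 members adjusted over the list alone. Fibroblast and matrix genes were lower by 0.73 ± 0.29 (17 of 20 lower, camera adjusted p = 2.35e-05, adjusted p = 0.543 with an estimated correlation), with -0.48 on slide 1, -0.97 on slide 2 and 5 members adjusted over the list alone. Myeloid suppressive effectors had -0.64 ± 0.24 (12 of 15 lower, camera adjusted p = 0.0121, adjusted p = 0.538 with an estimated correlation), with -1.03 on slide 1 and -0.24 on slide 2, and the call ended without untreated replicate 3 (adjusted p = 0.12) and with array weights (0.0542), in a range of 0.000177 to 0.538. S100a8, an alarmin of granulocytes in this list, had -2.76 ± 0.91 (adjusted p = 0.14), with -4.61 on slide 1 and -0.91 on slide 2. S100a9, its partner, had -1.44 ± 0.60 (adjusted p = 0.221, or 0.0444 with the slide as a block). The granulocytic list had -0.55 ± 0.23 and did not pass (adjusted p = 0.0575).

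Macrophage genes had -0.46 ± 0.22 (camera adjusted p = 0.0076, adjusted p = 0.764 with an estimated correlation), and the call ended without untreated replicate 1 (0.0567) and in the deposited value table (0.0785), in a range of 0.000177 to 0.764. Checkpoint genes had -0.33 ± 0.18 (camera adjusted p = 0.0121, adjusted p = 0.538 with an estimated correlation), and the call ended without untreated replicate 3 (-0.18, adjusted p = 0.228) and with array weights (0.0871), in a range of 0.00141 to 0.538. Genes of cytotoxic and NK cells had -0.33 ± 0.27 (camera adjusted p = 0.028, adjusted p = 0.764 with an estimated correlation). Their call ended with the slide as a block (0.0517), without 60-day replicate 1 (0.124) or 3 (0.0855) and without untreated replicate 3 (-0.14, adjusted p = 0.425), in a range of 0.000214 to 0.945. Gzma fell 2.79-fold (-1.48 ± 0.28, adjusted p = 0.0327), and 3 members fell when adjusted over the list alone. Mast cell genes had 0.26 ± 0.15 (camera adjusted p = 0.0305, adjusted p = 0.538 with an estimated correlation), and the call ended without 60-day replicate 1 (0.0857) or 2 (0.0649), resistant replicate 1 (0.0541) or untreated replicate 3 (0.115) or 4 (0.0519), in a range of 0.000862 to 0.706. MHC class I genes had -0.27 ± 0.22 (camera adjusted p = 0.0488, adjusted p = 0.893 with an estimated correlation). Their call ended with the slide as a block (0.0696), without 60-day replicate 1 (-0.16, adjusted p = 0.356) or 3 (0.0879), without resistant replicate 1 (0.0541) and without untreated replicate 3 (-0.12, adjusted p = 0.608), in a range of 0.0236 to 0.893. Within slides 1 and 2 these lists had -0.52 and -0.39, -0.56 and -0.09, -0.52 and -0.14, 0.17 and 0.35, and -0.38 and -0.16, in the order above. The T cell list had -0.07 (adjusted p = 0.564). Ccl2 had -1.09 ± 0.37, Csf1r -0.63 ± 0.35, Gzmb -0.63 ± 0.20 (above background in 1 of 4 60-day tumours), Ccr2 -0.55, Arg1 -0.45, Cd8a -0.30, Foxp3 -0.14, Cd274 -0.02 and Cd3e 0.08, none past the threshold.

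The same 25 genes rose and the same 68 fell at 4 and 60 days, against 0.319 and 0.939 if the calls were independent. In opposite directions 0 genes changed. The comparisons share the untreated tumours. Data simulated with no change gave 0 shared genes in 5 simulations, but held no change to share. With a separate pair of untreated tumours each, 7 or 8 of the 16 genes called at 4 days were shared. The log2 differences had a correlation of 0.887 across genes, 0.502 in simulated data and 0.643 with separate untreated tumours.

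The comparison of resistant with untreated tumours asks how far tumours that had escaped the drug differ from those never exposed. Only 4 of 21951 features changed. Adh1 rose 4.14-fold (2.05 ± 0.26, adjusted p = 0.011) and Pla2g5, a secreted phospholipase gene on chromosome 4 (138355185 to 138355244), rose 2.90-fold (1.54 ± 0.22, adjusted p = 0.0298). A pair of neighbouring unnamed transcripts on chromosome 8 fell, namely ENSMUST00000067018 (probe at 111772977 to 111773036), which fell (-1.63 ± 0.11, adjusted p = 2.59e-05), and a long noncoding RNA (probe at 111769436 to 111769495), which was above background in 0 of 4 resistant tumours and at least 1.71-fold lower (adjusted p = 0.000637). These transcripts have no gene name and are given as all 4 features past the threshold. Genes of the cell cycle, interferon response and cytotoxic cells were lower as groups by camera with a fixed correlation, but not with an estimated correlation (adjusted p = 0.584 for each) or by exact permutation (p = 0.0571, 0.0857 and 0.0857).

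Of these features, Adh1 had 2.17 on slide 1 and 1.93 on slide 2, Pla2g5 1.35 and 1.72, and ENSMUST00000067018 -1.51 and -1.75. With the slide as a block 14 passed, 6 higher and 8 lower, including all 4, and 2092 had an unadjusted p under 0.05. The groups did not overlap for 4.29% of all genes, where chance gives 2.86%, and the slides had a correlation of 0.201. The count was 14 without resistant replicate 1, 176 without untreated replicate 3, and 2 without resistant replicate 3 or untreated replicate 2 or 4. Adh1 passed in none of the last 3. Alternatives gave 0 (either slide alone) to 1938 (array weights). Only Adh1, higher, and the 2 chromosome 8 transcripts, lower, changed in all 3 comparisons with untreated tumours.

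Cell cycle genes were lower in 28 of 28 members in resistant tumours (-0.53 ± 0.21, camera adjusted p = 8.71e-16, adjusted p = 0.584 with an estimated correlation), with -0.18 on slide 1 and -0.88 on slide 2 (exact permutation p = 0.0571). Pcna and Mcm6, the brightest members, had -0.50 ± 0.14 and -0.43, and 9 members fell when adjusted over the list alone. Interferon response genes were lower by 0.53 ± 0.22 (24 of 26 lower, camera adjusted p = 6.68e-07, adjusted p = 0.584 with an estimated correlation), with -0.57 on slide 1, -0.48 on slide 2 (exact permutation p = 0.0857) and -1.02 ± 0.31 for Irf1. No member passed in limma or adjusted over the list alone. Genes of cytotoxic and NK cells were lower by 0.52 ± 0.27 (15 of 16 lower, camera adjusted p = 2.42e-05, adjusted p = 0.584 with an estimated correlation), with -0.39 on slide 1, -0.64 on slide 2, -0.32 without untreated replicate 3 and 2 members adjusted over the list alone. The chemokine gene Ccl5 had -0.96 ± 0.55 and Nkg7 -0.12. MHC class I genes had -0.38 ± 0.22 (camera adjusted p = 0.000993, adjusted p = 0.584 with an estimated correlation), with -0.29 on slide 1 and -0.47 on slide 2, and the call ended without untreated replicate 3 (-0.22, adjusted p = 0.15) and with array weights (0.0841), in a range of 6.27e-05 to 0.584.

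Granulocytic genes had a mean difference of 0.51 ± 0.43 in resistant tumours (camera adjusted p = 0.0375, adjusted p = 0.584 with an estimated correlation), which was -0.16 on slide 1, 1.18 on slide 2, and 0.19, 0.35 and 0.79 without resistant replicates 1, 2 and 3. The scores of resistant replicates 1 to 4 were 1.45, 0.98, -0.34 and -0.06. The call ended without resistant replicate 1 (adjusted p = 0.481) or 2 (0.133), 4-day replicate 3 (0.0557) or untreated replicate 1 (0.0565) or 3 (0.139), in a range of 0.00127 to 0.615. Erythroid genes, which mark blood, were higher in the same tumours (0.62 ± 0.43, camera adjusted p = 0.00999, adjusted p = 0.584 with an estimated correlation), at 0.32 on slide 1 and 0.92 on slide 2. That call ended without resistant replicate 1 (adjusted p = 0.106) or 2 (0.32, adjusted p = 0.131) or untreated replicate 3 (adjusted p = 0.15). The haemoglobin genes Hba-a1 and Hba-a2 had 0.66 ± 0.33 and 0.59 ± 0.30. S100a8 had 0.74 ± 0.91 (-0.10 on slide 1, 1.58 on slide 2) and S100a9 0.56 ± 0.60. The list of myeloid suppressive effectors had 0.29 ± 0.28 (adjusted p = 0.186), and that of myeloid chemokines 0.10 (0.92).

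MAPK output genes had a mean difference of -0.21 ± 0.08 in resistant tumours, lower in 10 of 16 members (camera adjusted p = 0.0441, adjusted p = 0.584 with an estimated correlation, exact permutation p = 0.0857), with -0.18 on slide 1 and -0.24 on slide 2. The call ended in 8 of 16 runs, without 4-day replicate 3 (0.0557) or 4 (0.05), resistant replicate 1 (0.106), 2 (0.115) or 3 (0.0599), or untreated replicate 2 (0.164), 3 (0.168) or 4 (0.0869), in a range of 0.0225 to 0.584. Dusp6 had -0.88 ± 0.19 (adjusted p = 0.127), Spry4 -0.91 ± 0.36 (0.417) and Etv5 -0.59, and 1 member fell when adjusted over the list alone. Pigment genes had 0.11 ± 0.31 (0.389), with 0.09 for Mitf, -0.16 for Tyr and -0.27 for Dct. Hair shaft genes had 0.25 ± 1.16 (0.386) and keratinocyte genes 0.03 ± 0.72 (0.92). The mean, median and camera differed in sign for the lists of nerve, resistance-linked receptor, macrophage and adipocyte genes, none of which passed. Of the 17 lists that passed camera, 7 up and 10 down, only cell cycle, interferon response and cytotoxic cell genes passed without any single array. Among the rest were fibroblast genes (-0.41 ± 0.40, -0.66 without resistant replicate 1, -0.68 without untreated replicate 3, and -0.20 and not called without resistant replicate 3, adjusted p = 0.254) and dendritic cell genes (-0.35 ± 0.32, -0.58 without resistant replicate 3, -0.01 on slide 1, and -0.18, -0.21 and -0.18 and not called without resistant replicates 1 or 2 or untreated replicate 3, adjusted p = 0.113, 0.0785 and 0.168). These were also lost with an estimated correlation, at an adjusted p of 0.718 and 0.584, the highest in their ranges of alternatives. Immediate early and heat shock genes had 0.23 ± 0.14 (camera adjusted p = 0.0233, not without resistant replicate 2, 0.14 with adjusted p = 0.106, or untreated replicate 1, adjusted p = 0.068) and sebaceous gland genes 0.66 ± 0.59 (0.00269, 1.23 without resistant replicate 1, 0.43 without replicate 2, not called without replicate 3, 0.0526). The other lists called were endothelial genes (0.32 ± 0.33, 0.53 without resistant replicate 3, and 0.17, 0.15 and 0.18 and not called without resistant replicates 1 or 2 or untreated replicate 3), hypoxia genes (0.26 ± 0.21, not without untreated replicate 4, 0.12), mast cell genes (0.39 ± 0.17, not without resistant replicate 1), T cell genes (-0.25 ± 0.23, not without resistant replicates 1 or 2 or untreated replicate 3, -0.06 without the last), MHC class II genes (-0.30 ± 0.19, not without resistant replicates 1 or 2 or untreated replicates 1 or 3) and checkpoint genes (-0.22 ± 0.19, not without resistant replicates 2 or 4 or untreated replicate 3, -0.07 without the last). With an estimated correlation the adjusted p of these 8 lists was 0.742 for T cell genes and 0.584 for each of the others. Mki67 had -0.74 ± 0.44 and Braf 0.04. Cd8a had -0.42, Gzmb -0.28, Ccl2 -0.26, Foxp3 -0.21, Csf1r -0.17, Cd3e -0.08, Cd274 0.03, Ccr2 0.15 and Arg1 0.32.

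The comparison of resistant with 4-day tumours sets escape against early response. Dbp was the only gene past the threshold, and it fell 9.28-fold (-3.21 ± 0.36, adjusted p = 0.00657), with -3.34 on slide 1 and -3.08 on slide 2. Lists of MAPK output and of myeloid suppressive effectors were higher in each resistant tumour than in any 4-day tumour. MAPK output genes were higher by 0.45 ± 0.10 (14 of 16 higher, camera adjusted p = 0.000129, adjusted p = 0.394 with an estimated correlation, exact permutation p = 0.0286), with 0.65 on slide 1 and 0.26 on slide 2. Ccnd1, which alone passed when adjusted over the list alone, had 1.53 ± 0.30 (adjusted p = 0.196), Spry4 0.96 ± 0.36, Etv5 0.37 and Dusp6 0.06.

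Myeloid suppressive effectors were higher by 0.69 ± 0.27 in resistant against 4-day tumours (14 of 15 higher, camera adjusted p = 3.07e-05, adjusted p = 0.401 with an estimated correlation, exact permutation p = 0.0286), with 0.35 on slide 1 and 1.03 on slide 2. S100a8 had 1.85 ± 0.91 (adjusted p = 0.632), S100a9 1.08 ± 0.60 and Arg1 0.95 ± 0.55, and 1 member rose when adjusted over the list alone. Granulocytic genes were higher by 0.98 ± 0.46 (15 of 16 higher, camera adjusted p = 3.07e-05, adjusted p = 0.401 with an estimated correlation, exact permutation p = 0.0857), with 0.55 on slide 1 and 1.42 on slide 2 and 2 members adjusted over the list alone. Erythroid genes in these tumours had 0.46 ± 0.46 (adjusted p = 0.0759). Myeloid chemokines had 0.78 ± 0.52 (camera adjusted p = 0.000284, adjusted p = 0.555 with an estimated correlation, exact permutation p = 0.2), with 0.03 on slide 1, 1.53 on slide 2, 0.36 without resistant replicate 1 and 0 of 18 members past the threshold, and Ccl2 had 0.89 ± 0.37. Hypoxia and glycolysis genes were higher by 0.32 ± 0.11 (15 of 17 higher, camera adjusted p = 0.00011, adjusted p = 0.481 with an estimated correlation), with 0.42 on slide 1, 0.22 on slide 2 and 2 members adjusted over the list alone. Pigment genes were lower by 0.77 ± 0.43 (13 of 16 lower, camera adjusted p = 2.99e-07, adjusted p = 0.401 with an estimated correlation), with -0.53 on slide 1, -1.01 on slide 2 and 4 members adjusted over the list alone. Mitf had -0.79 ± 0.20 (adjusted p = 0.397), Tyr -0.86 ± 0.32 and Dct -1.03 ± 0.70. Hair shaft genes were lower by 1.52 ± 0.84 (16 of 16 members, 0 past the threshold, camera adjusted p = 1.78e-07, adjusted p = 0.58 with an estimated correlation, exact permutation p = 0.114), with -0.46 on slide 1, -2.58 on slide 2 and -0.79 without resistant replicate 1.

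In all, 13 lists passed camera between resistant and 4-day tumours, 9 up and 4 down, of which these 7 passed without any single array. Adipocyte genes (-0.66 ± 0.56, adjusted p = 0.702 with an estimated correlation, -0.37 without 4-day replicate 1 and -1.15 without 4-day replicate 2) also did, but not in the deposited value table (0.353) or with processed signals of Feature Extraction (0.188), in a range of 1.21e-09 to 0.702. Macrophage genes (0.37 ± 0.37, camera adjusted p = 0.0056, adjusted p = 0.891 with an estimated correlation) had -0.07 on slide 1, 0.81 on slide 2 and 0.56 without 4-day replicate 3, and were not called without resistant replicate 1 (0.12, adjusted p = 0.461) or 4-day replicate 4 (0.19, adjusted p = 0.336), in a range of 7.75e-05 to 0.891. With limma, 1799 genes had an unadjusted p under 0.05, and 8 passed with the slide as a block. Alternatives gave 0 (these groups alone or either slide alone) to 33 (array weights). The count was 4 without 4-day replicate 2, 5 without 60-day replicate 1, and 2 without 4-day replicate 3 or 4 or resistant replicate 3. The groups did not overlap for 2.77% of all genes, where chance gives 2.86%, and the slides had a correlation of 0.0896. Next by p were Adamts4 (2.27 ± 0.33, adjusted p = 0.0655), the clock gene Arntl (1.59 ± 0.24, 0.0655), Tef (-1.80 ± 0.28, 0.0686) and the clock gene Ciart (-1.44 ± 0.24, 0.0835), all of which passed with the slide as a block (0.0316, 0.00439, 0.0316 and 0.0316). Other named genes had Csf1r 0.26, Ccr2 0.58, Mki67 -0.07, Foxp3 0.04, Cd3e 0.00, Cd274 0.37 and Braf -0.33. In 4-day tumours Gzmb and Cd8a were above background in 0 of 4.

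Between resistant and 60-day tumours, limma called 0 genes, with 1246 at an unadjusted p under 0.05 and a smallest adjusted p of 0.149. The slide correlation was 0.213. The count was 0 with the slide as a block, and 1 without resistant replicate 2 or with array weights. The smallest p among genes with a symbol outside predicted genes were those of Zcchc12 (-1.42 ± 0.30), Corin (-0.66 ± 0.14), Kcnj16 (-0.73 ± 0.16), Kif21a (-0.84 ± 0.19) and Skint9 (-0.75 ± 0.18), each at an adjusted p of 0.867. Myeloid suppressive effectors were higher by 0.93 ± 0.35 (14 of 15 higher, camera adjusted p = 2.03e-08, adjusted p = 0.253 with an estimated correlation), with 0.89 on slide 1 and 0.97 on slide 2 (exact permutation p = 0.0571). S100a8 had 3.50 ± 0.91 (4.50 on slide 1, 2.49 on slide 2), and 3 members rose when adjusted over the list alone. Granulocytic genes were higher by 1.06 ± 0.48 (14 of 16 higher, camera adjusted p = 1.1e-07, adjusted p = 0.267 with an estimated correlation), with 0.73 on slide 1, 1.38 on slide 2 and 3 members adjusted over the list alone. Erythroid genes had 0.41 ± 0.41 (camera adjusted p = 0.0441, adjusted p = 0.827 with an estimated correlation, 0.02 on slide 1, 0.66 without resistant replicate 3). Their call ended without resistant replicate 1 (0.29, adjusted p = 0.161) or 2 (0.11, adjusted p = 0.65), 60-day replicate 3 (0.29, adjusted p = 0.124) or 4 (adjusted p = 0.0824), 4-day replicate 4 (0.0546) or untreated replicate 3 (0.0502). Myeloid chemokines had 0.94 ± 0.50 (camera adjusted p = 1.13e-05, adjusted p = 0.448 with an estimated correlation, exact permutation p = 0.114; 0.41 and 1.48 on slides 1 and 2). Macrophage genes had 0.46 ± 0.32 (camera adjusted p = 5.73e-05, adjusted p = 0.727 with an estimated correlation, exact permutation p = 0.2; 0.27 and 0.64). Complement genes had 0.49 ± 0.27 (camera adjusted p = 0.000335, adjusted p = 0.556 with an estimated correlation, exact permutation p = 0.114), with 0.15 and 0.83 on the slides and 1.69 ± 0.60 for the complement gene C3. Hair shaft genes had -1.67 ± 0.78 (camera adjusted p = 3.87e-10, adjusted p = 0.516 with an estimated correlation, exact permutation p = 0.0286), with -0.53 and -2.80 on the slides. Pigment genes had -0.78 ± 0.35 (camera adjusted p = 7.52e-09, adjusted p = 0.35 with an estimated correlation, exact permutation p = 0.114), with -0.91 and -0.66. No member of these 5 lists passed in limma or adjusted over the list alone. Without resistant replicate 1 the differences were 0.51 for myeloid chemokines, 0.21 for macrophage, 0.27 for complement and -0.94 for hair shaft genes. Of the 13 lists called, 9 up and 4 down, these 5 and those of myeloid suppressive effectors and granulocytic genes passed without any single array.

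Between 60-day and 4-day tumours, limma called 0 genes, with 410 at an unadjusted p under 0.05 and a smallest adjusted p of 0.229. The slide correlation was 0.322. The count was 1 (Arntl) with the slide as a block, 1 without resistant replicate 2 or 4, and 2 with array weights. The clock genes Arntl (1.47 ± 0.24, adjusted p = 0.229) and Dbp (-2.12 ± 0.36, 0.266) had the smallest p among genes with a symbol. Of the lists, 5 passed camera, 3 up and 2 down. Cell cycle genes were higher at 60 days (0.26 ± 0.17, 27 of 28 members, camera adjusted p = 2.05e-07, adjusted p = 0.991 with an estimated correlation), with 0.32 on slide 1, 0.19 on slide 2 and 0.12 without 4-day replicate 3, but not with array weights (0.155), in a range of 4.13e-08 to 0.991. MAPK output genes were also higher (0.34 ± 0.15, 14 of 16 members, camera adjusted p = 0.00046, adjusted p = 0.396 with an estimated correlation, exact permutation p = 0.0857), with 0.42 on slide 1 and 0.25 on slide 2. Ccnd1 had 1.08 ± 0.30 and was past the threshold adjusted over the list alone. The other lists called were hypoxia genes (0.18 ± 0.12), adipocyte genes (-0.36 ± 0.56) and skeletal muscle genes (-0.54 ± 0.93), each with an adjusted p of 0.991 with an estimated correlation. Hypoxia genes were not called without 4-day replicate 3 (0.11) or 4 (0.20) or 60-day replicate 2 (0.09). Adipocyte genes were not called without 4-day replicate 1 (-0.07) or 4 (-0.27) or 60-day replicate 1 (-0.18), had -0.84 without 4-day replicate 2 and -0.60 without 60-day replicate 2, and had -0.72 on slide 1 and 0.00 on slide 2. Skeletal muscle genes were not called without 4-day replicate 1 (-0.24), 3 (-0.54) or 4 (-0.34) or 60-day replicate 3 (0.20), had -1.04 without 4-day replicate 2 and -0.94 without 60-day replicate 2, and had -1.55 on slide 1 and 0.48 on slide 2.

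A signature of the day-4 response, chosen on 1 slide and scored on the other, stood 0.75 ± 0.22 above untreated in 4-day tumours (SD 0.33, n = 4, exact permutation p = 0.0286) and 0.64 ± 0.16 above in 60-day tumours (exact permutation p = 0.0286), which is 85.8% of the day-4 shift. Resistant tumours stood 0.41 ± 0.19 above untreated, 54.0% of the shift (exact permutation p = 0.0857). The difference between resistant and 4-day tumours was -0.35 ± 0.21 (exact permutation p = 0.257), between resistant and 60-day tumours -0.24 ± 0.14 (exact permutation p = 0.143) and between 60-day and 4-day tumours -0.11 ± 0.18 (exact permutation p = 0.571). Only 15 of the 100 high and 10 of the 100 low genes were chosen on both slides. The 4-day score lost the threshold without 4-day replicate 1 (0.39, exact p = 0.0857) or 4 (0.47, 0.0857), resistant replicate 1 or 2 (0.75, 0.0857), or untreated replicate 2 (0.54, 0.0571), 3 (1.19, 0.114) or 4 (0.48, 0.0571). The 60-day score did so without 60-day replicate 1 (0.71, exact p = 0.0571), 2 (0.59, 0.0857) or 3 (0.64, 0.0571), and was 0.37 without untreated replicate 4 and 1.19 without untreated replicate 3. The resistant score passed without 4-day replicate 4 (0.52, exact p = 0.0286), was 0.73 without resistant replicate 1, 0.25 without 4-day replicate 1, and 0.23 without untreated replicate 2 or 4, so the percentages above are loose. Resistant and 4-day tumours differed without 4-day replicate 3 (-0.60, exact p = 0.0286), and resistant and 60-day tumours without untreated replicate 3 (-0.90, exact p = 0.0286), but without 4-day replicate 4 both differences turned sign (0.0429 and 0.0445, exact p = 0.457 and 0.571), and without resistant replicate 1 they were -0.02 and -0.04. That between 60-day and 4-day tumours turned sign without 4-day replicate 1 (0.0782), resistant replicate 1 or 2 (0.0225) or untreated replicate 3 (0.000998).

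**Figure D3:**
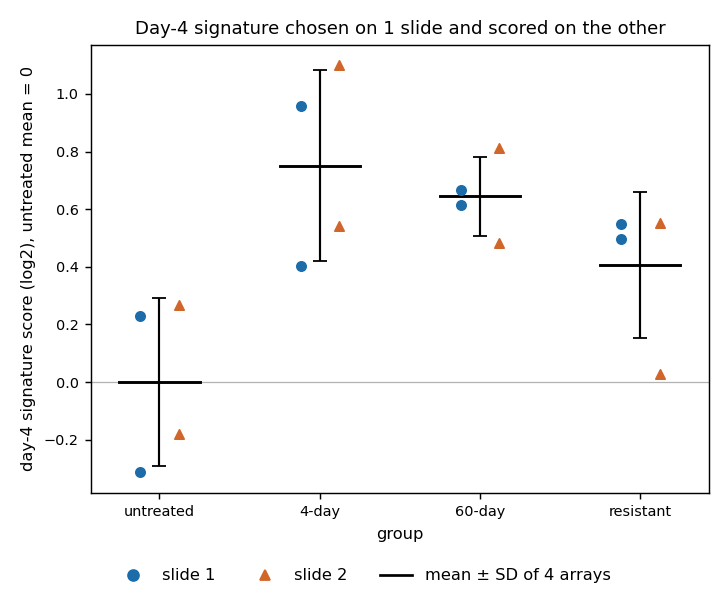
Score of the day-4 signature in log2 units relative to the untreated mean (y axis) for each tumour, by group (x axis), with circles for slide 1, triangles for slide 2 and lines for mean ± SD of 4 tumours. The 4-day and 60-day means are 0.75 and 0.64, and resistant replicate 1 lies near the untreated mean while the other 3 resistant tumours lie near 0.5.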

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

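The tests of patterns in this part were chosen after the results were seen, and the tests on regrouped arrays before. A gap between 1 array and the other 3 of its group is given as the distance from their mean. Such gaps were found in 10 of 212 groups, where about 1 in 20, or 10.6, would arise by chance.

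Resistant tumours of slide 2 (replicates 1 and 2) had higher granulocytic genes than those of slide 1. Slide 2 was higher in every group (0.08 in untreated, 0.54 in 4-day, 0.76 in 60-day and 1.42 in resistant tumours), so a slide effect could be part of it. A common effect would not produce all of it, since the difference in resistant tumours exceeded the mean of the others by 0.96 ± 0.20. Blood in the biopsy could also contribute, as erythroid genes differed between the slides by 1.25 ± 0.37 in resistant tumours, but untreated tumours had an erythroid difference of 0.65 with the granulocytic one of 0.08 (4-day -0.06, 60-day 0.48). The title codes follow the slides in this group, so a difference between animals or cages cannot be told apart from the slide, and more granulocytes in these tumours is an untested biological alternative.

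Genes of hair and sebaceous glands were higher in 60-day tumours. A lower share of tumour cells alone would raise all host cells alike. The sebaceous change exceeded the fibroblast one by 2.07 ± 0.45. Both had been seen before, so this is weak evidence against that cause. Normal skin in the biopsy may contribute, as keratinocyte genes differed by 0.61 ± 0.22. At 4 days the keratinocyte difference was 0.37 ± 0.32 (exact permutation p = 0.286), and normal skin cannot be told apart from other causes there.

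Myeloid suppressive effectors and MAPK output genes differed between resistant and 4-day tumours by 0.69 and 0.45. Hair shaft genes differed between resistant and 60-day tumours by -1.67. Exact permutation p, by which they were picked, was 0.0286 each, unadjusted over 32 lists. Dbp differed between resistant and 4-day tumours by -3.21. In resistant replicate 1 the day-4 signature score lay -0.50 from the rest, and sebaceous gland genes -2.27. Hair shaft genes lay 0.36 from the rest in 60-day replicate 2, and nerve genes 0.52 in 60-day replicate 1. Mitf lay -0.61 from the rest in resistant replicate 4, Dct 2.98 in resistant replicate 2, and Cd3e -1.31 in resistant replicate 3. Foxp3 lay 1.07 from the rest in untreated replicate 3 and 0.34 in 4-day replicate 2, and Cd8a 0.95 in untreated replicate 3.

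Each pair of groups was regrouped into all 35 splits of 4 and 4 arrays. For 60-day against untreated tumours, only the real split (1 of 35) gave 179 genes and the others gave 0. This share is the smallest possible, and with several comparisons and shared title codes it does not exclude chance. Nor do the other counts of genes. At 4 days 3 splits gave 293 or more, and the highest other, 4-day replicates 1, 2 and 4 with untreated replicate 3, gave 1302. For resistant against untreated tumours 3 splits gave 4 or more, and resistant replicate 1 with untreated replicates 1, 2 and 4 gave 1937. Both named splits exchange untreated replicate 3 for 1 treated array, and the cause was not tested. For resistant against 4-day tumours 3 splits gave 1 or more, with 4 as the highest other. All 35 splits gave 0 between resistant and 60-day tumours and between 60-day and 4-day tumours.

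For counts of lists chance cannot be excluded in any comparison. Splits with as many lists as the real one numbered 8 at 4 days (14, highest other 22), 8 at 60 days (15, highest other 21), 6 for resistant against untreated (17, highest other 20), 15 for resistant against 4-day (13, highest other 24), 20 for resistant against 60-day (13, highest other 21) and 30 for 60-day against 4-day tumours (5, highest other 19). The split by slide called 15 lists between resistant and 60-day tumours and 5 between 60-day and 4-day tumours, as many as the groups themselves or more.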

How the results depend on the processing

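With 4 arrays per group and between 49.1% and 54.2% of probes above background, small changes and dim genes were missed. In simulated data, limma recovered 22% of 1.5-fold and 92% of 4-fold changes between 4-day and untreated tumours. No label joins tumours of different groups, so no paired analysis was possible. The replicate numbers follow the order of the samples and the slide. The slide as a block removes only what the slides have in common over all groups, not a difference between title codes within a group. Named genes past the threshold kept their direction under every alternative. For the largest changes the naming rule ensures this without 1 array and on 1 slide alone. Named genes not past the threshold had the opposite sign in 917 values. Direction and side of the threshold held in 13562 values of named genes, passing or not, and in 5149 of lists. Of the largest changes, 8 of 20 at 4 days and 4 of 20 at 60 days passed without any single array. In resistant tumours 0 of 2 did. Counts of genes depended strongly on the processing. Each slide alone and array-score permutation were chosen after the data were seen. Apart from settings with fewer arrays, the cause was not tested for any of the changes below.

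Genes called at 4 days, at 60 days and in resistant tumours against untreated ones were 293, 179 and 4. With processed signals of Feature Extraction the first 2 counts were 71 and 28, and 8 lists were called between 60-day and 4-day tumours. Without background correction 8 genes were called between resistant and untreated tumours. Median centring gave 12, 12 and 1 genes. Cy5 alone gave 513 at 4 days, 13 in resistant tumours, and 7 between resistant and 4-day tumours. The deposited value table gave 105 and 74 genes, 11 lists for resistant against untreated tumours, 2 genes for resistant against 4-day tumours, and a day-4 signature of 0.85 at 4 days (exact permutation p = 0.0857). Probes above background on all arrays gave 10 lists for resistant against untreated and 3 genes for resistant against 4-day tumours. The mean of probes gave 2 genes for resistant against 4-day tumours.

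With the slide as a block 632, 615 and 14 genes were called against untreated tumours, 8 between resistant and 4-day, and 1 between 60-day and 4-day tumours. A model of only the groups compared gave 29, 1254 and 1, and 0 between resistant and 4-day tumours, where 1055 had an unadjusted p under 0.05. Array weights gave 4699, 5155 and 1938 genes, with 8 lists at 60 days and 9 in resistant tumours, and 33, 1 and 2 genes for resistant against 4-day, resistant against 60-day and 60-day against 4-day tumours.

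On slide 1 alone limma called 0 genes at 4 days, 0 at 60 days, 0 in resistant tumours and 0 between resistant and 4-day tumours, with 1533, 1424, 762 and 720 at an unadjusted p under 0.05, and 12 lists between 60-day and 4-day tumours. On slide 2 alone the counts were 0, 0, 0 and 0, with 3323, 3958, 3174 and 2647, and 9 lists were called at 60 days.

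With an estimated correlation camera called 0 lists in each of the 6 comparisons, with 2, 1, 1, 3, 3 and 1 at an unadjusted p under 0.05. Fry called 2, 0, 0, 0, 0 and 0, with 6, 6, 3, 5, 3 and 1. Exact permutation, unadjusted, gave 4, 6, 0, 2, 1 and 0. Camera with a fixed correlation, adjusted, called 14, 15, 17, 13, 13 and 5.

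With each array left out in turn, genes called ranged from 44 to 695 at 4 days, 22 to 1132 at 60 days, 2 to 176 in resistant tumours, 1 to 5 between resistant and 4-day tumours, 0 to 1 between resistant and 60-day tumours and 0 to 1 between 60-day and 4-day tumours. Lists ranged from 9 to 19, 8 to 16, 8 to 18, 9 to 15, 8 to 19 and 3 to 14 in the same order. The signature ranged from 0.39 to 1.19, 0.37 to 1.19, 0.23 to 0.73, -0.90 to 0.0429, -0.90 to 0.0445 and -0.21 to 0.0782.

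Some lists turned direction. Between resistant and 4-day tumours, cell cycle genes had -0.00496 with processed signals of Feature Extraction and -0.19 on slide 2, and ranged from -0.00629 (without 4-day replicate 3) to 0.22 with 1 array left out. Sebaceous gland genes ranged from -0.68 to 0.12 (without resistant replicate 1), and had 0.17 on slide 1, where macrophage genes had -0.0665, complement genes -0.0364 and endothelial genes -0.11. Between resistant and 60-day tumours, hypoxia genes had -0.0390 with median centring and -0.0230 on slide 2. Keratinocyte genes had 0.0698 with array weights and 0.21 on slide 1, and ranged from -0.96 to 0.0930 (without resistant replicate 1). On slide 1 fibroblast genes had -0.0215 and endothelial genes -0.0767. Between 60-day and 4-day tumours, skeletal muscle genes had 0.48 on slide 2 and ranged from -1.04 to 0.20 (without 60-day replicate 3). Between resistant and untreated tumours, granulocytic genes had -0.16 on slide 1.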

Other observations

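The clock group below was put together, and its tests chosen, after the results were seen. Many genes of the circadian clock rose in 4-day tumours, and Arntl fell. Of 10 genes that the clock drives or that repress it, 8 rose at 4 days, namely Dbp, Tef, Hlf, Nr1d1 (1.51 ± 0.22, adjusted p = 0.00553), Nr1d2 (2.83-fold, adjusted p = 0.0409), Ciart (1.66 ± 0.24, adjusted p = 0.00521), Per2 (1.14 ± 0.21, adjusted p = 0.0232) and Cry2 (1.02 ± 0.17, adjusted p = 0.0153). Per1 and Per3 had 1.38 and 0.85 (adjusted p = 0.0612 and 0.0784). Arntl, which encodes the activator BMAL1, fell by 1.48 ± 0.24 (adjusted p = 0.0119). The mean of the 10 genes was 1.58 ± 0.20 higher at 4 days (at least 1.56 on each slide), 0.55 ± 0.24 higher at 60 days and 0.06 ± 0.17 higher in resistant tumours. No p is given for these means, as the genes were grouped after their rise was seen.

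Collection at another time of day could give this pattern, and so could an effect of the inhibitor on the clock, which was not tested. The genes Arntl, Clock, Npas2 and Nfil3, which peak in the opposite phase, had a mean of -0.52 ± 0.20, but only Arntl passed, and Npas2 had 0.25. Collection times are not given in the sources used here, and the 4-day tumours have a series of title codes of their own. A slide effect would not give the pattern, as the difference between these sets was at least 2.01 within each slide. Skin appendages in the biopsy would not either, since that difference was lower at 60 days than at 4 days (-1.55 ± 0.44) while hair and sebaceous genes stayed high.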
